A study of Arabidopsis thaliana with 18 samples.

How the data were processed

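Total RNA of rosette leaves from 18 samples (2 genotypes, 3 times, 3 biological replicates each) was labelled with Cy3 from 0.2 µg per the labels and hybridized to 1 array per sample. Per the file headers, the scanner's intensity values come from Agilent Feature Extraction 10.7.3.1 on array design 021169, with 45220 spots, 43803 of them outside the controls, and no such spot was saturated. Per the file headers, the processed intensity used here is the scanner signal after Feature Extraction's background subtraction, in arbitrary units. The deposited table holds log2 values that the authors made by subtracting each array's 75th percentile and then a baseline per probe, as tested against the scanner values. For 43556 probes, table and scanner values differed by a constant per probe within a genotype, with a median SD of 0.00158 over the WT and 0.00123 over the mutant columns. The mutant baseline was the median of all 18 arrays (median absolute difference over probes 0.000572). The WT baseline was another value, which is not given in the sources used here and differed from it by a median of 0.133. This difference correlated across probes with mutant minus WT (r = 0.693), so differences between genotypes were not taken from that table. Its column medians were 0.0526, -0.0441 and -0.0137 for WT 0 h, 0.0961, 0.0534 and 0.0438 for WT 2 h, 0.0164, 0.0178 and -0.0509 for WT 4 h, 0.0008, -0.0070 and 0.0068 for mutant 0 h, -0.0204, -0.1065 and 0.0282 for mutant 2 h, and -0.1459, -0.0391 and -0.0389 for mutant 4 h. Scale and direction are known from this match, and the centring of the WT columns stays unknown.

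Values were recomputed from the scanner files. Spots that the scanner software marked as outliers were left out, spots of a probe were averaged, log2 was taken, and each array's 75th percentile was subtracted. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which left 28974 probes. Of 43603 probes, 36475 were assigned to 26166 loci, 34348 by transcript accession, 1414 by locus code and 713 by symbol. Symbols came from a reference gene table of assembly TAIR10.1, used for names only, while coordinates are those of the array's TAIR10 annotation. There were 475 probes that named several loci, and 7128 had no locus. A gene was represented by its brightest tested probe, which gave 20372 genes. Of 6507 genes with several tested probes, 108, 118, 21, 28, 50, 11, 86, 88, 87, 3 and 12 had probes called in opposite directions in the 11 comparisons, in the order of WT 2 h and 4 h against 0 h, WT 4 h against 2 h, the same 3 in the mutant, mutant against WT at 0, 2 and 4 h, and the differences between responses at 2 and 4 h.

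All 18 arrays were fitted together with limma 3.58.1 (lmFit and eBayes, two-sided moderated test, 12 residual and 1.79 prior degrees of freedom) with 1 mean per group. Adjusted p are Benjamini-Hochberg values over the 20372 genes, and a gene was called at an adjusted p under 0.05. Where no array of the dimmer group measured a gene above background, the change is given as at least N-fold: the mean of the brighter group against the dimmer group with each of its arrays raised to the lowest signal that was well above background on that array. Where only some arrays did, their number is given.

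There were 37 gene lists of 594 members, written from general knowledge and fixed, like the tests, the alternatives and the rule for naming genes, before the data were examined. The reference gave the symbol of 7 members to another locus and these were dropped, and 575 were measured. Lists cover type-A and other type-B response regulators, cytokinin signalling, cytokinin metabolism and other cytokinin-induced genes, ABA receptors, PP2C phosphatases, kinases and bZIP factors, and ABA metabolism. They also cover dehydration and LEA genes, DREB factors, osmolyte synthesis, flavonoid and anthocyanin genes, cuticle, photosynthesis, chlorophyll synthesis, senescence, dark and sugar starvation, jasmonate, salicylate and immunity, ethylene, auxin response, antioxidant enzymes, heat shock, aquaporins, cell-wall growth, clock, ribosomal proteins and glucosinolates. The 8 marker lists are for guard cell, phloem, xylem, trichome, shoot apex, cell division, root and flower. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 37 lists, and again with an estimated correlation. With slide as a fixed block only the preset correlation was used. Of 333 list medians in the 9 comparisons of pairs of groups, 33 moved by 0.1 or more when genes below background were set at their bound, the largest by 1.24. A bound was never let past 0, so that 0 medians changed sign is nearly built in. In the mutant against WT at 0 h, the PP2C median went from 0.45 to 0 and the dehydration median from 0.23 to 0. Names were given to the 6 genes with a symbol and the 3 without one that had the largest called change in each direction among genes whose arrays did not overlap (8 with a symbol for differences between responses, with no such condition), to the 4 most significant members of each list, to a panel of 43 genes and to the disrupted genes. The text prints part of these.

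Calls were tested on simulated data, with 200 genes changed by 1.5, 2 or 4-fold in each comparison among 20372. Of genes changed 2-fold, 47.8% were recovered in the simulation of WT at 2 h, 71.6% for the mutant at 2 h, 56.7% for the mutant against WT at 0 h, 29.9% for the difference between responses at 2 h and 41.8% at 4 h. Of genes changed 4-fold, 81.8%, 87.9%, 84.8%, 75.8% and 72.7% were recovered in these comparisons. Each gene had the same SD in all simulated groups, so the comparisons of pairs of groups differ only by the genes and noise drawn. Far more genes were called in the data than were changed here, so these shares do not give the recovery in the data. Unchanged genes made up from 1.83% (WT 2 h against 0 h) to 9.3% (mutant 4 h against 0 h) of the calls, and over 5% in 8 of the 11 comparisons. Overlaps of calls were set beside the number that independent calls would give and, where comparisons share WT 0 h, beside 20 simulations with that shared control. Intervals are 95% bootstrap intervals over the genes of a list from 10000 draws, or t intervals over arrays, on each array's median of gene values minus their mean over all arrays, where so named.

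Alternatives tried were quantile normalization, the array median in place of the 75th percentile, normexp background correction with an offset of 50, the authors' table, no filter on dim probes, only probes well above background on all 18 arrays, outlier spots kept, eBayes with trend and robust, array quality weights, a replicate block, slide as a random block, slide as a fixed block where it could be fitted, comparison within one slide, only the groups of a comparison in the fit, the mean of all probes of a gene, a threshold of 0.01, a minimum of 2-fold, an estimated list correlation and leaving out each array in turn. Leaving out the mutant arrays with anther transcripts at 0 h and 4 h together was chosen after seeing the data. Slide and scan day are per the file headers. R 4.3.3, data.table (version 1.17.8), statmod 1.5.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used. Protein levels, hormone levels and plant phenotypes were not analysed here.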

Results

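Messenger RNA of rosette leaves from 24-day-old Arabidopsis thaliana was measured on 18 one-colour Agilent arrays. Plants were wild type (WT) or the arr1,10,12 triple mutant, which lacks 3 type-B response regulators, the transcription factors that turn on genes after a cytokinin signal. Detached shoots were left to dry for 0, 2 or 4 h, and each of the 6 groups holds 3 biological replicates per the labels. No group holds undried shoots at 2 or 4 h. Changes from 0 h, called responses to drying here, therefore cannot be told apart from time since detachment or the time of day. The number of arrays limits the precision of every value given here. Between 67.2% and 73.1% of the spots of an array were well above background, and the 75th percentile of the signal lay between 849 and 1685 units. Arrays of a WT group correlated across genes at r = 0.982 or more, and arrays of a mutant group at r = 0.951 or more. Genes are not independent replicates in such a correlation. Log2 changes are given with their standard error (SE) and come from 3 arrays per group. The SE rests on 1 spread per gene shared by all 18 arrays, so it does not follow the spread of the groups compared. Those spreads differ: the median SD per gene was 0.0855 in WT 0 h and 0.236 in mutant 2 h. A list's value is the median log2 change of its measured genes.

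The arrays lie on 6 slides and were scanned on 2 days. All 9 WT arrays share 1 scan day and all 9 mutant arrays the other, and no slide holds both genotypes. Every difference between mutant and WT at a given time therefore cannot be told apart from the slide and the scan day. The WT 0 h arrays are alone on slide 1, so the WT arrays cannot tell changes from 0 h apart from that slide. Slide 2 holds WT 2 h with 1 array of WT 4 h, slide 5 holds 2 arrays each of mutant 0 h and mutant 2 h, and slide 6 holds mutant 4 h with 1 array of mutant 2 h. Within slide 5 the dehydration, jasmonate and PP2C lists rose at 2 h by medians of 3.90, 3.00 and 4.12. These values argue against slide 1 as the whole cause of the rises of those lists in WT. Its part in their size stays open. Part of the mutant arrays also carried transcripts of the anther tapetum, the tissue that feeds developing pollen. The mean log2 level of 10 anther genes, listed after such genes had been seen, was -1.42 in replicate 3 of mutant 0 h, -1.64 in replicate 2 of mutant 4 h, and -3.42, -1.82 and -1.18 in the 3 arrays of mutant 2 h. It lay between -7.40 and -6.01 in the other 13 arrays. LAP5, for example, makes pollen-wall precursors and read 1.15 in replicate 3 of mutant 0 h against -6.87 and -6.91 in the other arrays of that group.

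**Figure D1:**
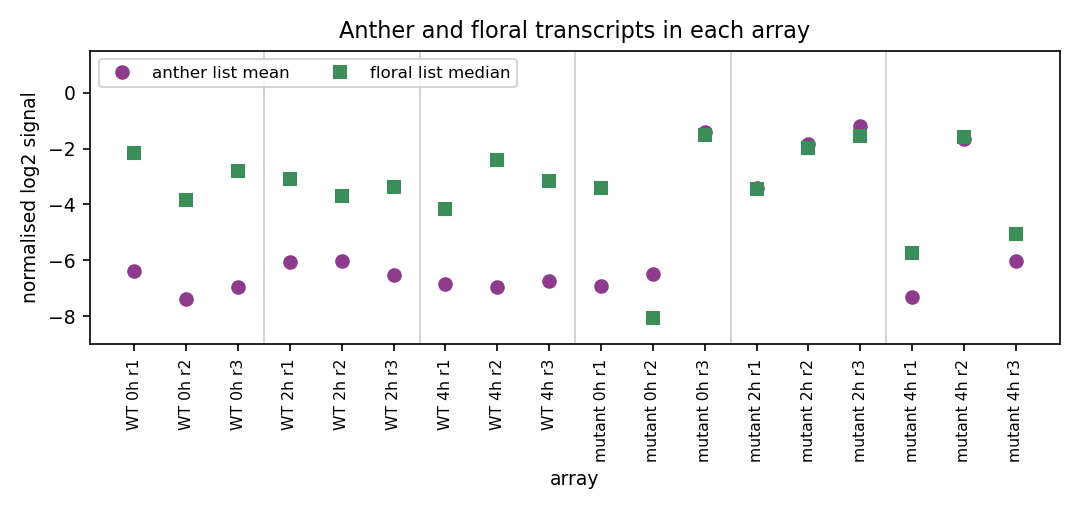
Circles show the mean normalized log2 signal of 10 anther genes and squares the median of the 10 floral genes in each of the 18 arrays. Anther means of 5 mutant arrays lie between -3.42 and -1.18 and those of the other 13 arrays between -7.40 and -6.01, while floral medians of WT arrays lie between -4.16 and -2.17.

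The genes disrupted in the mutant were read first, at all 3 times. At 0 h, ARR12 (AT2G25180) was at least 66-fold lower in the mutant (adjusted p = 1.84e-07), since no mutant 0 h array measured it above background. ARR10 (AT4G31920) was lower by log2 -4.88 ± 0.30 (SE, adjusted p = 7.41e-07) and ARR1 (AT3G16857) by -3.80 ± 0.264 (adjusted p = 1.44e-06). At 2 h the differences were -6.14 ± 0.333 for ARR12, which 1 of the 3 mutant arrays measured, -4.89 ± 0.30 for ARR10 and -2.86 ± 0.264 for ARR1. At 4 h they were -5.12 ± 0.333, -4.26 ± 0.30 and -2.71 ± 0.264, all past the test. No array was out of place: the highest mutant array read -5.02 for ARR12, -2.52 for ARR10 and -2.23 for ARR1, and the lowest WT array read -0.78, 0.33 and -0.52. The TAIR10 annotation of the array places the ARR10 probe on chromosome 4 from 15444292 to 15444351 and the ARR1 probe on chromosome 3 from 5758781 to 5758840. It gives the ARR12 probe a span on chromosome 2 from 10724301 to 10724311, shorter than the probe itself. Another ARR12 probe, from 10724676 to 10724735, was lower by -6.32 ± 0.301 at 0 h, with 2 of 3 mutant arrays above background. Another ARR1 probe, from 5758871 to 5758930, was lower by -4.41 ± 0.261. The ARR1 and ARR10 probes stayed well above background on all mutant arrays.

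**Figure D2:**
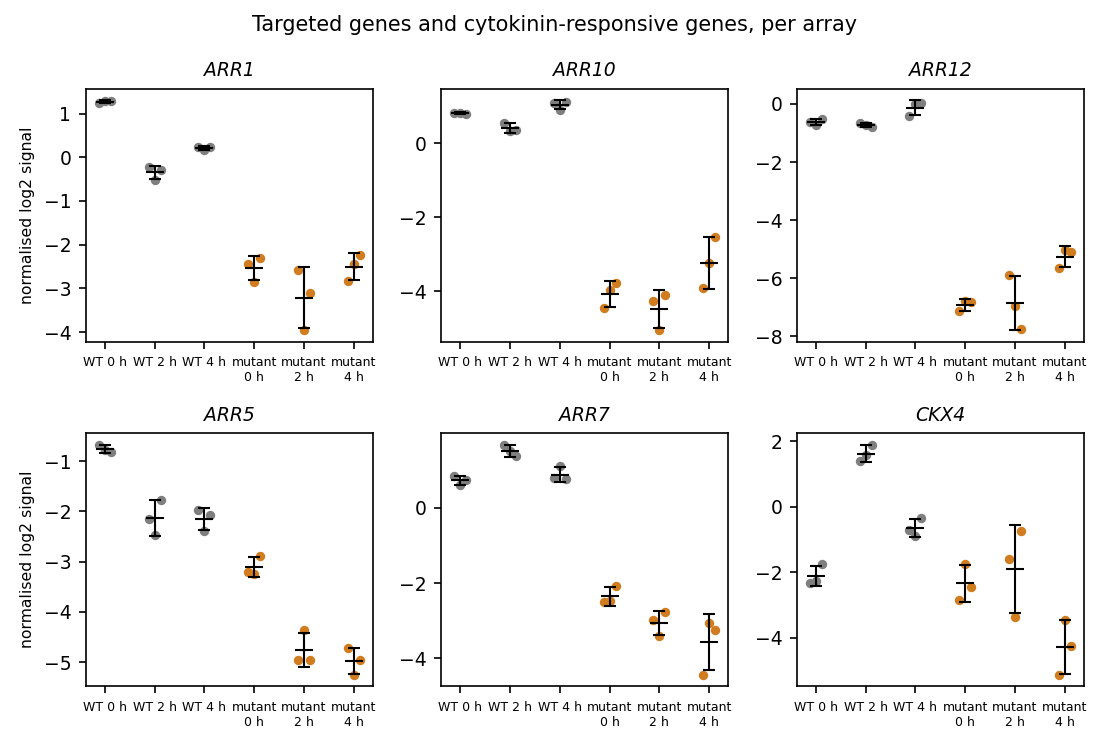
Points show normalized log2 signal of each array for the disrupted genes and cytokinin-induced genes, by group, with the mean and SD of 3 arrays. The highest mutant array lies below the lowest WT array for ARR1 (-2.23 against -0.52), ARR10 (-2.52 against 0.33) and ARR12 (-5.02 against -0.78).

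The mutant was compared with WT before drying to ask which genes depend on ARR1, ARR10 and ARR12 in watered plants. Cytokinin-responsive genes stood lower. Type-A response regulators, the early cytokinin-induced genes that dampen the signal, fell as a group by a median of -3.09, with 0 of 9 higher and 8 lower. ARR15 was lower by -5.48 ± 0.402 (1 of 3 mutant arrays measured it), ARR16 by -4.37 ± 0.329, ARR7 by -3.09 ± 0.282 and ARR5 by -2.35 ± 0.203 (adjusted p = 5.98e-06). Other cytokinin-induced genes fell by a median of -0.83, with 0 of 12 higher and 8 lower, or 1 and 9 adjusted over the list alone. Among them the GATA factor CGA1 was lower by -2.48 ± 0.32 and UGT76C2, which conjugates cytokinin to glucose, by -1.69 ± 0.157. The flowering gene FT was at least 17.1-fold lower and SOC1 lower by -1.64. The largest other falls with a symbol were RL6 at -5.31 and P1R3 at -4.51. Both cytokinin lists passed camera (adjusted p = 1.12e-07 and 0.000813), and both also passed at adjusted p = 0.0114 and 0.031 with an estimated correlation. With the type-A gene that no mutant array measured set at its bound, the type-A median was -2.85.

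Defence-related genes stood higher in the watered mutant. Glucosinolate genes, which make sulphur-rich defence compounds, rose by a median of 1.88, with 16 of 18 higher and 0 lower. MYB29, a regulator of the pathway, was higher by 2.74 ± 0.24 (adjusted p = 6.69e-06) and CYP79F1 by 3.57 ± 0.407. Jasmonate genes rose by 1.15, with 19 of 30 higher and 0 lower (19 and 1 adjusted over the list alone). LOX2, an enzyme of jasmonate synthesis, was higher by 1.83 ± 0.249 and JAZ10, a repressor that jasmonate induces, by 1.75 ± 0.202. Salicylate and immunity genes rose by 1.84, with 13 of 21 higher. PR1 was higher by 6.74 ± 1.61 (adjusted p = 0.00526), FMO1 by 6.78 ± 1.27 (1 of 3 WT arrays measured it), and BGLU22 was at least 34.9-fold higher. Flavonoid genes rose by 1.16, with 15 of 27 higher: PAP1 (AT1G56650), which switches on anthocyanin synthesis, was higher by 4.23 ± 0.46 and CHS by 2.37. NRT2.6 was higher by 6.03 (1 of 3 WT arrays) and NRT1.8 by 5.78 ± 0.464 (2 of 3). Camera gave adjusted p of 1.37e-08 for glucosinolate, 9.35e-06 for jasmonate, 4.4e-05 for flavonoid and 0.000209 for salicylate genes. None of the 4 passed with an estimated correlation: adjusted p = 0.486 for the first 3 and 0.573 for salicylate genes.

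Other shifts at 0 h reached the clock, auxin, vessel and ribosome lists. Clock genes fell by a median of -0.45, with 4 higher and 12 lower of 21 (5 and 13 adjusted over the list alone): the evening gene LUX was lower by -1.04 ± 0.0694 and TOC1 by -1.0 ± 0.126, while the morning genes LHY and CCA1 were higher by 1.98 ± 0.212 and 1.44 ± 0.179. Auxin-response genes fell by -1.42, with 1 higher and 7 lower of 13 (1 and 8 adjusted over the list alone), such as IAA4 at -1.51. Xylem markers fell by -0.76, with 6 of 9 lower (7 adjusted over the list alone). Ribosomal protein genes rose by 0.32, with 8 of 18 higher (9 adjusted over the list alone). Their camera adjusted p were 0.024, 0.0129, 0.00453 and 0.00228, and 0.486, 0.573, 0.486 and 0.695 with an estimated correlation. The dehydration list did not pass (median 0.23, 13 higher and 10 lower of 37, adjusted p = 0.712), nor did abscisic acid (ABA) metabolism (0.03), although NCED3, which makes the rate-limiting enzyme of ABA synthesis, was lower by -1.64 ± 0.124 (adjusted p = 2.11e-06). RAB18 (AT5G66400), a dehydrin, was lower by -1.58 ± 0.451 and RD29B higher by 1.86. The fall of RAB18 lay in mutant replicates 2 and 3 (-0.91 and -1.38), while replicate 1 read 0.91, near the WT arrays (1.03 to 1.23). Markers of other tissue did not pass at 0 h: root 2.05 (PYK10 2.82), flower -1.14, guard cell -0.22, phloem 0.04 and trichome -1.49. Heat-shock genes had a median of 1.17, or 0.34 with genes below background set at their bound, and did not pass. In total 3980 genes were higher and 3577 lower, 2809 of the 7557 by 2-fold or more (1929 higher, 880 lower). Higher calls made up 52.7%, but 42.6% with the array median, 47.2% with quantile normalization, 48.8% with normexp, 49.0% with probes above background on all arrays and 49.5% with array weights, which called 13035 genes. In camera, 10 of 37 lists passed. Arrays of the 2 genotypes did not overlap for 57.1% of genes, against 10% by chance.

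In WT, 2 h of drying were compared with 0 h to ask which genes change first. The largest list median was that of jasmonate genes, which rose by 4.93, with 29 of 30 higher and 0 lower. JAZ10 rose by 6.41 ± 0.202 (adjusted p = 3.27e-10), JAZ1 by 6.03 ± 0.237 and LOX2 by 3.75 ± 0.249. Of the jasmonate-inactivating genes, CYP94B1 was at least 1550-fold higher and CYP94B3 up by 11.34 ± 0.798. UGT76E12 was at least 1920-fold higher and BSMT1, which makes volatile methyl esters, at least 385-fold. Dehydration and LEA genes, whose products protect drying cells, rose by 3.64, with 34 of 37 higher and 0 lower: RD29A by 6.35 ± 0.361, RD20 by 7.59 ± 0.407 and RAB18 by 3.06 ± 0.451. In ABA metabolism, NCED3 rose by 3.88 ± 0.124 (adjusted p = 3.27e-10) beside the ABA-degrading CYP707A1 at 2.1 ± 0.346, and the list rose by 1.51 with 12 of 13 higher and 1 lower. All 9 clade A PP2C phosphatases, which ABA induces and which restrain its signal, rose, by a median of 3.58 and with HAI1 at 8.57 ± 0.442. DREB factors rose by 1.96 (9 of 9, DREB2A 5.22 ± 0.425) and osmolyte genes by 3.13, with 11 higher and 2 lower of 15 (P5CS1, for proline, 3.70 ± 0.369).

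Among the falls at 2 h in WT, EXPA8, an expansin that loosens the cell wall, fell by 7.93 (1 of 3 WT 2 h arrays measured it), BBX14 fell by 5.31 ± 0.231 and XTH33 was at least 16.7-fold lower. The GATA factors GNC and CGA1 fell by 3.28 ± 0.186 and 3.00. Other list rises were in flavonoid genes (2.52, 18 higher and 1 lower of 27, or 19 and 1 adjusted over the list alone), heat-shock genes (2.96, 12 higher and 1 lower of 17) and aquaporins (1.90, 9 higher and 2 lower of 13). Senescence genes rose by 1.36 (10 higher and 3 lower of 19), with the chlorophyll-breakdown gene NYE1 up by 2.53 ± 0.208. Cuticle genes rose by 0.61 (15 higher and 2 lower of 31), ethylene genes by 0.86 (7 of 12 higher) and glucosinolate genes by 0.72 (10 higher and 2 lower of 18). With genes below background at their bound, the flavonoid median was 1.75. The other 24 lists did not pass. Their medians were -0.93 for type-A regulators (1 higher and 5 lower of 9), -1.91 for other type-B regulators, 0.65 for cytokinin signalling, 0.52 for cytokinin metabolism, 0.92 for other cytokinin-induced genes, -1.25 for ABA receptors and 0.00 for ABA kinases and their bZIP factors. They were 0.00 for photosynthesis, -0.44 for chlorophyll synthesis, -1.54 for dark and sugar-starvation genes, 0.40 for salicylate, 0.13 for antioxidant enzymes, -1.0 for cell-wall growth, 0.07 for the clock and 0.16 for ribosomal proteins. Auxin genes had a median of 0.31 and a mean of -0.26. Marker medians were -0.40 for guard cell, 0.14 for phloem, 0.44 for xylem, 0.49 for trichome, -0.28 for shoot apex, -0.05 for cell division, 0.19 for root and -0.30 for flower.

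In total 5398 genes rose and 6847 fell in WT at 2 h, 6088 of the 12245 by 2-fold or more, where rises were the larger part (3200 against 2888). Rises were also the larger part without the filter on dim probes (54.0%, against 44.1%) and with normexp (50.4%). Arrays did not overlap for 73.2% of genes. Camera adjusted p were 1.26e-18 for jasmonate, 3.07e-16 for dehydration, 5.96e-07 for PP2C, 8.7e-05 for ABA metabolism, 0.000398 for DREB, 0.0014 for osmolyte, 5.43e-05 for flavonoid and 0.000419 for heat-shock genes. They were 0.0121 for aquaporins and senescence, 0.015 for cuticle, 0.0172 for ethylene and 0.0248 for glucosinolate genes. None of the 13 lists passed with an estimated correlation: adjusted p = 0.159 for jasmonate, 0.162 for the dehydration, PP2C, DREB, osmolyte and heat-shock lists, 0.121 for ABA metabolism, and 0.445, 0.693, 0.599, 0.798, 0.496 and 0.778 for the flavonoid, aquaporin, senescence, cuticle, ethylene and glucosinolate lists.

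At 4 h in WT the dehydration programme stood higher still against 0 h, and leaf function genes were down. Dehydration genes rose by a median of 5.29, with 35 higher and 1 lower of 37 (36 and 1 adjusted over the list alone), or 4.90 with genes below background at their bound. RAB18 rose by 5.48 ± 0.451 (adjusted p = 1.42e-07), LEA4-5 was at least 217-fold higher and TSPO rose by 11.27 ± 0.904. NCED3 rose by 4.78 ± 0.124, HAI1 by 10.01 ± 0.442, P5CS1 by 6.28 ± 0.369 and JAZ10 by 5.38 ± 0.202. Jasmonate genes were up by 3.91 (29 of 30), PP2C genes by 5.28 (9 of 9), ABA metabolism by 2.79 (12 higher, 1 lower), DREB by 3.03 (7 of 9), osmolyte genes by 2.75 (11 higher, 2 lower) and heat-shock genes by 2.90 (12 higher, 2 lower). With such genes at their bound the PP2C median was 4.54 and that of ABA metabolism 2.02. Flavonoid genes rose by 2.22 (22 higher, 1 lower), senescence genes by 1.38 (12 higher and 3 lower, or 13 and 3 adjusted over the list alone; NYE1 4.29 ± 0.208), cuticle genes by 0.78 (18 higher, 3 lower), aquaporins by 1.68 (9 higher and 3 lower, or 9 and 4 adjusted over the list alone) and glucosinolate genes by 0.92 (11 higher and 3 lower, or 12 and 3 adjusted over the list alone).

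Photosynthesis genes fell at 4 h in WT by a median of -0.52, with 0 higher and 20 lower of 43 (16 adjusted over the list alone), and chlorophyll synthesis genes by -1.13, with 8 of 13 lower. PETE1, the electron carrier plastocyanin, fell by 2.00 ± 0.271, LHCB4.2 by 2.2 and CHLM by 2.38 ± 0.266. EXPA8 was at least 403-fold lower and GASA6 fell by 6.67 ± 0.598. In total 6244 genes rose and 7609 fell, 7559 of them by 2-fold or more (45.1% of calls rose, but 50.8% with the array median), and arrays did not overlap for 80.6%. Camera adjusted p were 1.24e-16 for dehydration, 1.44e-13 for jasmonate, 3.07e-07 for PP2C, 2.73e-05 for ABA metabolism, 6.84e-05 for flavonoid, 0.00206 for senescence, 0.00242 for osmolyte and heat-shock, 0.0027 for DREB and cuticle, 0.0277 for photosynthesis and chlorophyll, and 0.0475 for aquaporin and glucosinolate genes. None of the 14 passed with an estimated correlation: adjusted p = 0.206 for dehydration, jasmonate, PP2C and osmolyte, 0.0774 for ABA metabolism, 0.54 for flavonoid and senescence, 0.275 for heat-shock, 0.274 for DREB, 0.885 for photosynthesis, and 0.756 for the cuticle, chlorophyll, aquaporin and glucosinolate lists.

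**Figure D3:**
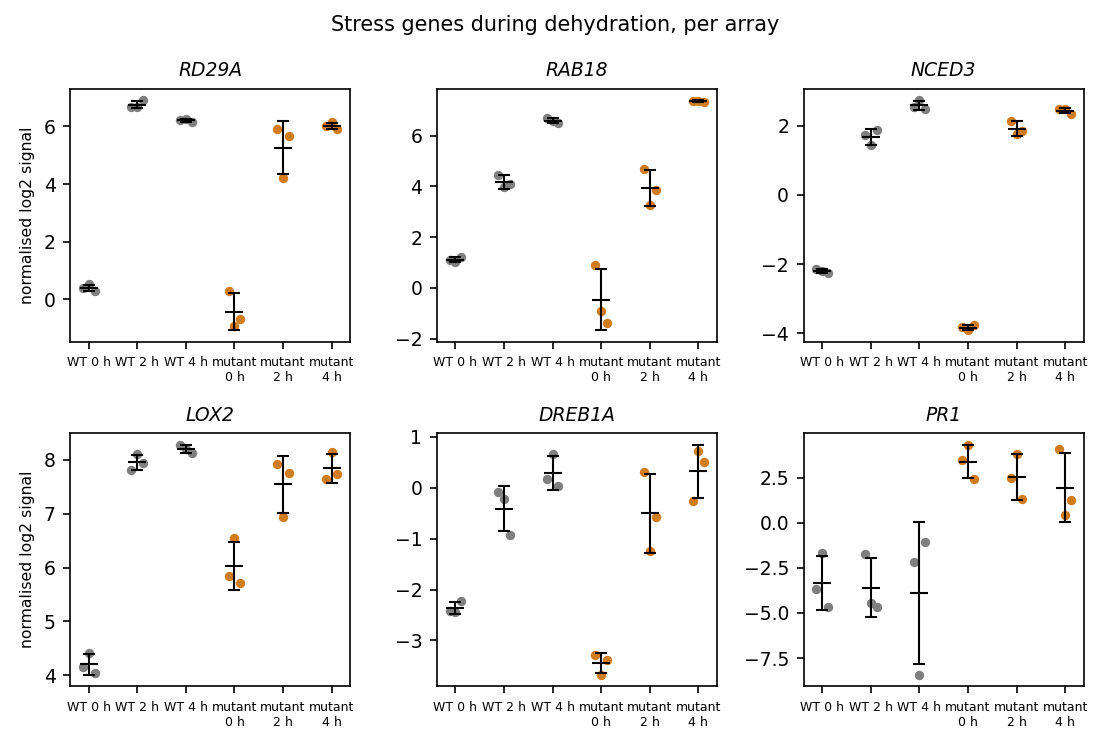
Points show normalized log2 signal per array for 6 stress genes in the 6 groups, with the mean and SD of 3 arrays. NCED3 rises from 0 to 2 h by 3.88 in WT and by 5.75 in the mutant, and LOX2 by 3.75 and 1.51.

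Between 2 and 4 h in WT, dehydration genes kept rising and jasmonate genes came down. The dehydration list rose by 0.68 (18 higher and 2 lower, or 19 and 2 adjusted over the list alone), with RD29B up by 3.52 ± 0.363, RAB18 by 2.42 ± 0.451 (adjusted p = 0.0011) and P5CS2 by 2.15 ± 0.204. Jasmonate genes fell by -0.80 (5 higher and 17 lower, or 5 and 18 adjusted over the list alone): the hormone-oxidising CYP94B1 and CYP94C1 fell by 3.15 ± 0.382 and 2.36 ± 0.242, and OPR3 by 1.98 ± 0.247. PP2C genes rose by 0.92 (7 of 9, or 8 adjusted over the list alone), ABA metabolism by 0.63 (7 of 13), senescence genes by 0.75 (9 higher, 2 lower) and ABA kinases by 0.43 (2 of 8). Photosynthesis genes fell by -0.52 (6 lower, or 2 adjusted over the list alone) and chlorophyll genes by -0.64 (6 lower), such as CHLM by 1.24. SAG29, a senescence-associated sugar transporter, had the largest rise with a symbol (5.81 ± 0.869). In total 3773 genes rose and 3447 fell, 2259 by 2-fold or more, and 54.7% of genes did not overlap. The share that rose, 52.3%, was 44.5% without the filter on dim probes, 48.4% with normexp, 48.8% with array weights, 49.3% with slide as a random block and 49.1% with only these groups in the fit.

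With slide as a block, 1335 genes rose and 775 fell between 2 and 4 h in WT, and within slide 2 (1 array against 3) limma called 0 genes, with 4927 at an unadjusted p under 0.05. The blocked list medians, which equal those within slide 2, were 0.63 for dehydration, -0.75 for jasmonate, 0.85 for PP2C, 0.47 for ABA metabolism, 0.80 for senescence, -0.71 for photosynthesis and -0.84 for chlorophyll genes. Their blocked adjusted p were 7.19e-07, 0.00364, 0.00197, 0.00861, 0.00646, 6.84e-07 and 0.00407, against 2.76e-05, 0.00295, 0.00118, 0.00834, 0.02, 4.78e-05 and 0.0283 without the block. With the block the estimate rests on 1 WT 4 h array against 3, so a lower adjusted p there is not stronger evidence. Fewer members were called in each list with the block. Dehydration genes had 12 higher and 1 lower, jasmonate genes 0 and 7, and senescence genes 6 and 1. PP2C and ABA metabolism genes had 2 higher each, and photosynthesis and chlorophyll genes 1 lower each. The ABA kinase list moved from adjusted p = 0.0321 to 0.0642 with the block (median 0.34), and the auxin list from 0.0783 to 0.0275 (median -1.0, 0 genes called). None of the 8 passed with an estimated correlation: adjusted p = 0.688 for ABA metabolism, 0.943 for ABA kinases and 0.993 for the others.

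In the mutant, 2 h of drying raised many of the genes that rose in WT. NCED3 rose by 5.75 ± 0.124 (adjusted p = 3.04e-12), RD29A by 5.69 ± 0.361, RAB18 by 4.41 ± 0.451 and PP2CA by 3.23 ± 0.123. JAZ10 rose by 4.73 ± 0.202 and LOX2 by 1.51 ± 0.249. The largest rises with a symbol were BSMT1 at 9.56 and PUB19 at 9.10 (each measured on 1 of 3 mutant 0 h arrays) and DIP2 at 8.20 ± 0.655. Dehydration genes rose by a median of 3.68 (35 of 37, or 36 higher and 1 lower adjusted over the list alone), jasmonate genes by 3.22 (29 of 30), PP2C genes by 3.86 (9 of 9), ABA metabolism by 1.42 (12 higher, 1 lower), DREB by 2.95 (9 of 9; 2.23 with genes at their bound), heat-shock genes by 1.88 (9 higher, 1 lower), osmolyte genes by 1.85 (9 higher, 2 lower) and flavonoid genes by 1.70 (15 higher, 1 lower). Senescence genes rose by 1.52 (11 higher, 1 lower), with the leaf-ageing factors NAP and NAC092 at 3.26 and 3.37 ± 0.197. Aquaporins rose by 1.60 (9 of 13), ethylene genes by 1.02 (7 of 12) and cuticle genes by 0.50 (10 higher, 3 lower). ABA receptors fell by -1.48, with 1 higher and 7 lower of 9 (PYL4 fell by 3.51), and chlorophyll genes by -0.60 (6 of 13 lower). HBI1, a growth-promoting factor, fell by 6.66 ± 0.526 and BBX14 by 5.33 ± 0.231. Flower markers had a median of 1.54 and root markers of -2.33 (-1.52 with genes at their bound), and neither passed. All 3 arrays at 2 h and 1 at 0 h carried anther transcripts.

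In total 4272 genes rose and 6114 fell in the mutant at 2 h, 4674 by 2-fold or more (2379 up, 2295 down). Rises were 41.1% of calls but 50.7% with the array median (4991 up, 4853 down), and 54.1% of genes did not overlap. With slide as a block 8239 genes were called, and within slide 5 (2 arrays against 2) 966. Blocked and within-slide list medians were equal: 3.90 for dehydration, 3.00 for jasmonate, 4.12 for PP2C, 1.79 for ABA metabolism, 1.52 for flavonoid, 1.68 for senescence, 3.07 for DREB, 2.57 for heat-shock, 0.42 for cuticle, 1.56 for osmolyte, 0.98 for ethylene, 1.14 for aquaporin, -1.54 for ABA receptor and -0.74 for chlorophyll genes. All 14 passed camera both ways, with the largest adjusted p at 0.0292 (chlorophyll) without the block and 0.0184 with it. With the block ABA kinases (0.93, adjusted p = 0.0171, against 0.0655 without it) and photosynthesis genes (-0.50, 0.0171 against 0.111) passed too, at the preset correlation, the only one used with the block. None of the 14 passed with an estimated correlation: adjusted p = 0.109 for dehydration, jasmonate, PP2C and DREB, 0.0535 for ABA metabolism, 0.167 for heat-shock, osmolyte and ABA receptor genes, 0.319 for flavonoid, 0.274 for senescence, 0.343 for ethylene, 0.664 for cuticle and aquaporin, and 0.688 for chlorophyll genes.

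At 4 h the mutant showed a broad fall of photosynthesis genes beside the dehydration response. Photosynthesis genes fell by a median of -0.97, with 0 higher and 39 lower of 43, such as PETE1 by 2.69 ± 0.271 (adjusted p = 1.62e-06). All 13 chlorophyll synthesis genes fell, by a median of -2.03 and with HEMA1, the first committed step, down by 2.44 ± 0.179. All 18 ribosomal protein genes fell, by -0.47. Dehydration genes rose by 5.23 (36 of 37; 4.96 with genes at their bound), with RAB18 up by 7.82 ± 0.451 and NCED3 by 6.27 ± 0.124 (adjusted p = 9.27e-13). PP2C genes rose by 4.39 (9 of 9), jasmonate genes by 2.36 (27 of 30), ABA metabolism by 1.95 (12 higher, 1 lower), ABA kinases by 1.60 (6 of 8; OST1, which closes stomata, 2.15 ± 0.162), DREB by 2.89 (8 of 9; 1.65 with genes at their bound) and heat-shock genes by 2.85 (13 higher, 2 lower). Flavonoid genes rose by 2.44 (22 higher, 1 lower), osmolyte genes by 1.74 (10 higher, 3 lower), senescence genes by 0.90 (8 higher, 3 lower) and cuticle genes by 0.67 (15 higher, 2 lower), while ABA receptors fell by -1.84 (7 of 9). HSFA6B was at least 222-fold higher, GASA3 at least 126-fold, and LEA7 rose by 11.36 and SAG29 by 10.73, each measured on 2 of 3 mutant 0 h arrays.

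Across the mutant at 4 h against 0 h, 5849 genes rose and 7027 fell, 6229 by 2-fold or more (45.4% of calls rose, but 56.6% with the array median), and 63.8% did not overlap. With slide as a block 7268 genes were called. No slide holds both groups, so the blocked estimate joins slides 5 and 6 through mutant 2 h. On slide 6 it rests on 1 array of mutant 2 h, replicate 3, whose anther mean was -1.18. Blocked medians were 5.21 for dehydration, 1.98 for jasmonate, 4.64 for PP2C, -1.4 for photosynthesis, 2.64 for ABA metabolism, 1.94 for flavonoid, -2.39 for chlorophyll, 3.03 for heat-shock, -0.78 for ribosomal, 2.39 for DREB, 2.23 for ABA kinase, -1.75 for ABA receptor, 1.51 for senescence and 1.63 for osmolyte genes. These 14 lists passed both ways, with largest adjusted p of 0.00659 (osmolyte) without the block and 0.00295 with it. The block left fewer members called in part of them: 6 flavonoid, 17 jasmonate and 4 DREB genes higher and 28 photosynthesis genes lower. PP2C genes kept their 9. The cuticle list moved from adjusted p = 0.00891 to 0.0873 as its median went to 0.36, and the glucosinolate list from 0.0874 to 0.0446 as its median went from -0.94 to -1.15. None of the 15 passed with an estimated correlation: adjusted p = 0.16 for dehydration, PP2C, ABA kinase and ABA receptor genes, 0.174 for jasmonate, heat-shock and DREB, 0.0657 for ABA metabolism, 0.195 for osmolyte, 0.433 for flavonoid, 0.473 for chlorophyll, 0.583 for senescence, 0.71 for photosynthesis and ribosomal, and 0.782 for cuticle genes. Replicate 2 at 4 h and replicate 3 at 0 h carried anther transcripts.

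Between 2 and 4 h in the mutant, ribosomal protein genes fell by -0.50, with 16 of 18 lower (18 adjusted over the list alone), such as RPS6A by 0.79 ± 0.13. Photosynthesis genes fell by -0.65 (24 of 43, or 30 adjusted over the list alone), chlorophyll genes by -1.04 (10 of 13, or 12 adjusted over the list alone) and jasmonate genes by -0.76 (16 of 30, JAZ10 by 1.71 ± 0.202). Dehydration genes rose by 0.93 (24 higher and 1 lower, or 25 and 1 adjusted over the list alone), with RAB18 up by 3.41 ± 0.451 and the late-embryogenesis gene EM1 by 4.2 ± 0.304. ABA kinases rose by 0.47 (4 of 8, or 6 adjusted over the list alone) and ABA metabolism by 0.52 (7 of 13). Ethylene genes fell by -0.58 (7 of 12) and cell-division markers by -0.97 (3 of 8, or 5 adjusted over the list alone; CYCB1;1 by 1.53). GASA3 rose by 4.62 ± 0.31. The largest falls without a symbol, AT3G52130 at -6.61, AT5G62080 at -6.56 and AT3G07450 at -5.77, were each measured on 1 of 3 arrays at 4 h, and anther transcripts were high in that group in 1 array against 3 at 2 h.

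In total 4443 genes rose and 3591 fell between 2 and 4 h in the mutant, 2452 by 2-fold or more, of which 1036 rose and 1416 fell, with 44.3% not overlapping. With only these groups in the fit 2965 genes were called. With slide as a block 4082 genes were called, and within slide 6 (3 arrays against 1) limma called 0, with 4309 at an unadjusted p under 0.05. Blocked and within-slide medians were -0.93 for photosynthesis, -0.66 for ribosomal, 0.77 for dehydration, -0.99 for jasmonate, -1.33 for chlorophyll, 0.61 for ABA kinase, -1.35 for cell-division and 0.55 for ABA metabolism genes, with blocked adjusted p of 2.28e-09, 6.08e-09, 1.03e-06, 6.53e-06, 5.23e-06, 0.0042, 0.0153 and 0.00986. Without the block they were 2.74e-07, 3.78e-07, 3.88e-07, 2.19e-05, 2.21e-05, 0.0156, 0.0342 and 0.0447. With the block the estimate rests on 3 arrays against 1, so a lower adjusted p there is not stronger evidence. The block left fewer members called in part of these lists. It called 0 cell-division markers, 10 photosynthesis and 10 jasmonate genes lower, and 16 dehydration and 2 ABA metabolism genes higher. Ribosomal (16 lower) and chlorophyll genes (10 lower) kept their counts. The ethylene list moved from adjusted p = 0.0342 to 0.298 (median -0.50), and the aquaporin list from 0.101 to 0.0062 as its median went from -0.57 to -1.02 (1 of 13 lower with the block). None of the 9 passed with an estimated correlation: adjusted p = 0.752 for photosynthesis, ethylene and cell division, and 0.705 for the others.

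**Figure D4:**
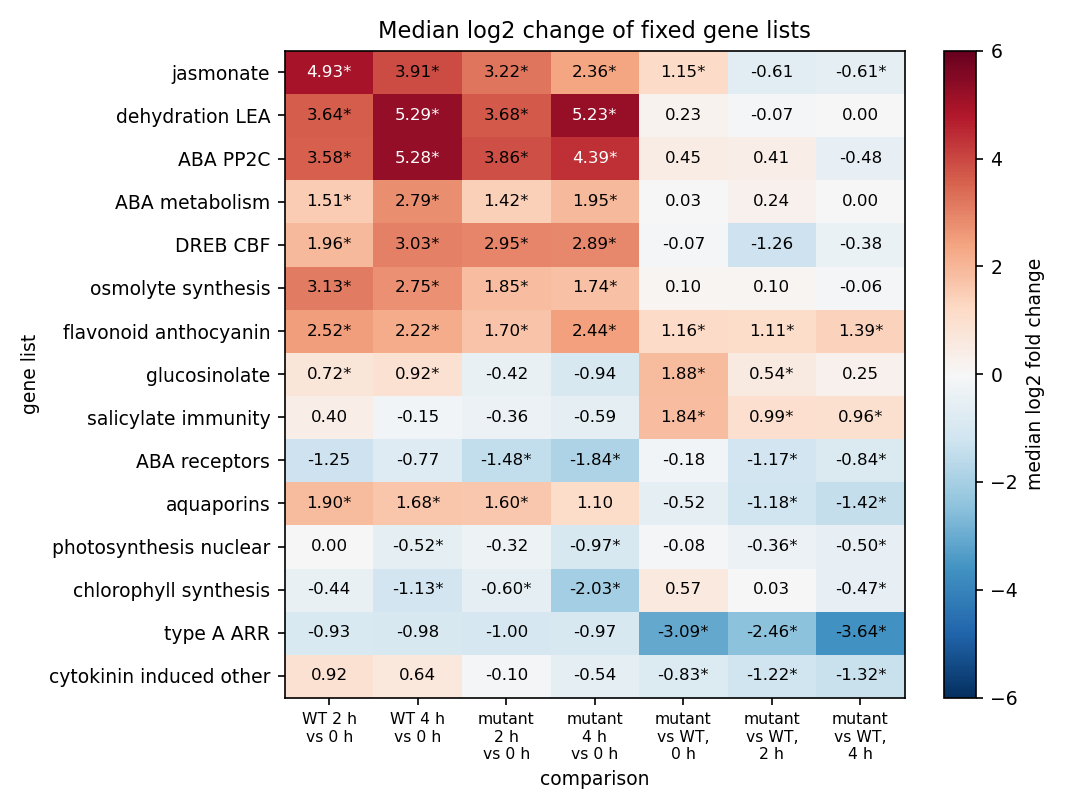
Each cell shows the median log2 change of a fixed gene list (vertical axis) in one comparison (horizontal axis), with an asterisk where camera gave an adjusted p under 0.05 at the preset correlation. Type-A regulators lie at -3.09, -2.46 and -3.64 in mutant against WT at 0, 2 and 4 h, and jasmonate genes at 1.15, -0.61 and -0.61.

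At 2 h of drying, the mutant was compared with WT to ask what cytokinin-dependent differences look like under stress. Type-A regulators were lower by a median of -2.46 (8 of 9), with ARR7 at -4.57 ± 0.282 (adjusted p = 8.21e-07) and ARR15 at least 25.7-fold lower. Other cytokinin-induced genes were lower by -1.22 (9 of 12, or 10 adjusted over the list alone): the cytokinin receptor AHK4 by -1.99 ± 0.229, UGT76C2 by -2.75 ± 0.157 and the cytokinin oxidase CKX4 by -3.52 ± 0.547. ABA receptors were lower by -1.17 (7 of 9), such as PYL7 at -1.58 ± 0.191, and aquaporins by -1.18 (9 of 13, or 10 adjusted over the list alone), such as TIP2;2 at -1.72. Clock genes fell by -0.31 (1 higher, 9 lower; LUX -1.12 ± 0.0694), photosynthesis genes by -0.36 (6 lower, or 2 adjusted over the list alone) and xylem markers by -0.71 (2 lower, or 4 adjusted over the list alone). Flavonoid genes rose by 1.11 (8 of 27), salicylate genes by 0.99 (7 of 21, or 8 adjusted over the list alone; PR1 6.16 ± 1.61), glucosinolate genes by 0.54 (5 of 18) and ribosomal protein genes by 0.22 (4 of 18). Dehydration genes did not pass (-0.07, 5 higher and 8 lower), with RD29A at -1.49 ± 0.361 and RD29B at 1.51. NCED3 (0.24) did not pass, nor did the jasmonate list (-0.61, adjusted p = 0.0846). FT was lower by -5.20. All 3 mutant arrays carried anther transcripts: AMS was at least 23.2-fold and AT5G62080 at least 197-fold higher, LAP5 was higher by 6.11 ± 1.95, and the flower markers had a median of 1.31 and a mean of 0.65 while camera gave a downward direction (adjusted p = 0.974).

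In total 3162 genes were higher and 3563 lower in the mutant at 2 h, 2269 by 2-fold or more (1261 higher, 1008 lower), and 44.9% did not overlap. The 6725 calls became 2432 with only these groups in the fit, 2962 from the authors' table and 10931 with slide as a random block, and higher calls 36.2% with normexp and 36.4% without the filter on dim probes, against 47.0%. Camera adjusted p were 4.54e-08 for type-A, 0.000194 for other cytokinin-induced, 0.00161 for flavonoid and aquaporin, 0.00428 for ABA receptor, 0.00735 for photosynthesis and salicylate, 0.00876 for clock, 0.0191 for ribosomal, 0.0219 for glucosinolate and 0.0387 for xylem genes. The cytokinin lists also passed at adjusted p = 0.00784 and 0.0105 with an estimated correlation. The other 9 did not: adjusted p = 0.779 for flavonoid, aquaporin and xylem, 0.149 for ABA receptor, 0.945 for photosynthesis, 0.922 for salicylate and glucosinolate, 0.299 for clock and 0.937 for ribosomal genes, each with an estimated correlation.

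At 4 h the mutant differed from WT in cytokinin, water-channel and ABA-receptor genes. Type-A regulators were lower by -3.64 (8 of 9), with ARR7 at -4.46 ± 0.282 (adjusted p = 1.3e-06) and ARR16 at -3.91. Other cytokinin-induced genes were lower by -1.32 (7 of 12, or 8 adjusted over the list alone), with UGT76C2 at -3.15 ± 0.157 and AHK4 at -2.50 ± 0.229. Cytokinin metabolism genes were lower by -0.57 (2 higher and 7 lower of 24, or 3 and 7 adjusted over the list alone). Aquaporins were lower by -1.42 (10 of 13, or 11 adjusted over the list alone), such as PIP2C at -2.40 ± 0.355, and ABA receptors by -0.84 (7 of 9), such as PYL7 at -2.16 ± 0.191. Photosynthesis genes were lower by -0.50 (11 of 43, or 3 adjusted over the list alone), chlorophyll genes by -0.47 (1 higher, 3 lower), jasmonate genes by -0.61 (2 higher and 11 lower, or 2 and 12 adjusted over the list alone), ribosomal protein genes by -0.29 (1 higher, 9 lower), clock genes by -0.40 (7 of 21) and xylem markers by -0.40 (4 of 9). Flavonoid genes were higher by 1.39 (15 of 27; CHS 3.15) and salicylate genes by 0.96 (3 of 21, or 2 adjusted over the list alone; PR1 5.84 ± 1.61, with 2 of 3 WT arrays above background). Within the dehydration list, which had a median of 0.00 and did not pass, EM1 and EM6 were higher by 3.84 ± 0.304 and 2.22. NUDT24 was at least 128-fold higher and BGLU24 at least 37.7-fold, while NAP was lower by -1.77 ± 0.208 and SAG12 at least 6.61-fold lower. Root markers (1.81, or 1.4 with genes at their bound; COBL9 at least 2.12-fold higher) had an adjusted p of 0.0522, and senescence genes (-0.35) one of 0.0505.

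Counts at 4 h were 3250 genes higher and 2810 lower in the mutant, 2049 by 2-fold or more, with 46.7% not overlapping. The authors' table gave 2477 calls and slide as a random block 9501. Higher calls were 53.6%, but 45.5% with normexp and 49.5% without replicate 3 of mutant 0 h and replicate 2 of mutant 4 h. Camera adjusted p were 8.8e-09 for type-A, 4.81e-05 for other cytokinin-induced, 1.7e-05 for photosynthesis and aquaporin, 4.78e-05 for flavonoid, 0.00041 for ABA receptor, 0.0051 for clock, 0.00593 for jasmonate and ribosomal, 0.0273 for salicylate, 0.0404 for xylem, 0.0429 for chlorophyll and 0.0465 for cytokinin metabolism genes. The first 2 lists also passed at adjusted p = 0.00546 and 0.0087 with an estimated correlation. The other 11 did not: adjusted p = 0.0626 for ABA receptor, 0.226 for clock, 0.29 for cytokinin metabolism, 0.626 for aquaporin and flavonoid, 0.751 for xylem, and 0.797 for photosynthesis, jasmonate, ribosomal, salicylate and chlorophyll genes, each with an estimated correlation.

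Whether the mutant responded differently to 2 h of drying was tested as the mutant response minus the WT response, whose sign does not give the size of a response. Jasmonate genes rose in both and less in the mutant, with a median difference of -1.63, with 0 of 30 higher and 14 lower (21 adjusted over the list alone): LOX2 by -2.24 ± 0.352 (adjusted p = 0.00329) and the sulphotransferase ST2A by -2.92 ± 0.427. Glucosinolate genes differed by -1.13 (7 of 18 lower, or 10 adjusted over the list alone), with medians of 0.72 in WT and -0.42 in the mutant, and with MYB29 at -3.24 ± 0.34. ABA receptors, which had medians of -1.25 in WT and -1.48 in the mutant, differed by -1.36 (3 of 9 lower, or 5 adjusted over the list alone), with PYL7 at -1.79 ± 0.27. NCED3 rose more in the mutant, by 1.87 ± 0.175 (adjusted p = 0.000157), from its lower level at 0 h. The leaf-ageing factors NAP and NAC092 rose more by 1.55 ± 0.295 and 1.30. Dark and sugar-starvation genes had a difference of 1.38 (2 of 8 higher, or 5 adjusted over the list alone; ASN1 1.67), from medians of -1.54 in WT and 0.22 in the mutant. Within the dehydration list, which did not pass (-0.31), RD20, LTI30 and RD22 had differences of -2.31, -2.03 and -1.33 ± 0.221. ABA kinases (0.41, 1 of 8, or 2 adjusted over the list alone), senescence genes (0.39, 2 higher, or 3 higher and 1 lower adjusted over the list alone) and photosynthesis genes (-0.34, 0 called) also passed, but none of the 7 lists did with an estimated correlation (adjusted p of 0.471 or more). The cytokinin receptor AHK4 had a difference of -1.25 and IPT3, which makes cytokinin, one of -2.67 ± 0.487.

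Altogether 623 genes had a positive and 1134 a negative difference at 2 h, 1010 of them of 2-fold or more. The 1757 calls became 965, 977 and 1043 without WT 0 h replicates 1, 2 and 3, 1135 without mutant 0 h replicate 2, 1072 with only these groups in the fit, 3682 with slide as a random block and 4243 with array weights. Camera adjusted p were 1.62e-11 for jasmonate, 1.33e-06 for glucosinolate, 0.00558 for dark and sugar-starvation, 0.006 for ABA receptor, 0.0213 for photosynthesis, and 0.0313 for ABA kinase and senescence genes. None of the 7 passed with an estimated correlation: adjusted p = 0.55 for jasmonate, 0.663 for glucosinolate and dark and sugar-starvation, 0.471 for ABA receptor, 0.897 for photosynthesis and senescence, and 0.568 for ABA kinase genes. The mutant arrays at 2 h all carried anther transcripts.

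By 4 h the same test gave 2114 genes with a positive and 1913 with a negative difference, but of the 1813 of 2-fold or more 670 were positive and 1143 negative. Slide as a random block gave 8199 calls and array weights 8472. Jasmonate genes rose less in the mutant, by -1.57 (20 of 30, or 22 adjusted over the list alone), with JAZ10 at -2.36 ± 0.286 and ST2A at -3.57. Glucosinolate genes differed by -1.80 (14 of 18 lower, or 1 higher and 15 lower adjusted over the list alone), with medians of 0.92 in WT and -0.94 in the mutant, and with MYB29 at -3.79 ± 0.34 (adjusted p = 6.23e-05). Ribosomal protein genes had a median of 0.06 in WT and fell in the mutant, a difference of -0.52 (12 of 18 lower, or 14 adjusted over the list alone). Chlorophyll genes, with medians of -1.13 in WT and -2.03 in the mutant, differed by -0.78 (3 of 13 lower, or 4 adjusted over the list alone; HEMA1 -1.43 ± 0.253). The photosynthesis list had a median difference of -0.42, but 1 of its 43 genes passed (RCA -1.01), or 0 adjusted over the list alone. ABA receptors, with medians of -0.77 in WT and -1.84 in the mutant, also differed by -0.77 (4 of 9, or 5 adjusted over the list alone; PYL7 -2.37 ± 0.27). ABA kinases had a difference of 0.63 (5 of 8 higher, or 5 higher and 1 lower adjusted over the list alone), with OST1 at 1.02. NCED3 rose more by 1.49 ± 0.175 (adjusted p = 0.000263), RAB18 by 2.33 ± 0.637 (adjusted p = 0.0207), and HAI1 less by -2.77 ± 0.625. RAB18 read 0.91, -0.91 and -1.38 in the mutant 0 h arrays, so the size of its difference depends on the array it starts from. The morning clock genes CCA1 and LHY had differences of -2.04 ± 0.253 and -1.93 ± 0.299, and TOC1 one of 0.79. Aquaporins did not pass as a list (-0.46, adjusted p = 0.0648), while PIP2C differed by -3.40.

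Camera adjusted p at 4 h were 2.08e-10 for jasmonate, 1.86e-07 for glucosinolate, 6.46e-07 for ribosomal, 0.00137 for photosynthesis, 0.00173 for chlorophyll, 0.0108 for ABA receptor and 0.0452 for ABA kinase genes. None of the 7 passed with an estimated correlation: adjusted p = 0.457 for jasmonate and ABA receptor, 0.51 for glucosinolate and ABA kinase, 0.674 for ribosomal, 0.994 for photosynthesis and 0.819 for chlorophyll genes. Differences between responses carry the 0 h difference between the genotypes with the opposite sign, as at MYB29, which stood 2.74 higher in the mutant at 0 h.

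Genes that changed in both genotypes nearly all moved the same way. At 2 h, 3544 genes rose and 4956 fell in both, against 1132 and 2055 if the calls were independent, and 83 moved in opposite directions, so 99.0% of 8583 went one way. At 4 h, 4617 rose and 5560 fell in both, against 1793 and 2625, and 97.5% of 10439 went one way. Across genes the responses correlated at r = 0.837 (rho = 0.802) at 2 h and r = 0.849 (rho = 0.82) at 4 h. The difference of the mutant at 0 h was also compared with the WT response. Of 5092 genes called in both at 2 h, 84.3% moved the same way, 2035 up and 2256 down (1055 and 1202 if the calls were independent), as PAP1, JAZ10 and LOX2 did, while NCED3 was among the 801 that went opposite ways. Of 5437 called in both at 4 h, 80.4% moved the same way, 2180 up and 2191 down (1220 and 1336). Both contrasts use the WT 0 h arrays, and 20 simulations with that shared control and no true change gave a correlation of 0.497. Sharing a control alone builds in such a value, so the measured 0.453 at 2 h and 0.446 at 4 h are not weighed against it. The simulations called 0 genes in the same direction in both contrasts. They hold no true change, so how much of the excess over independent calls the shared control adds among changed genes stays open. The measured covariance was 0.639 at 2 h and 0.709 at 4 h, against 0.0587 and 0.0588 simulated. The simulations hold no shift of slide 1, where the WT 0 h arrays lie alone, and such a shift would enter both contrasts with the same sign. The excess in covariance and the shared directions therefore cannot tell a likeness of the watered mutant to dried WT apart from that slide.

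**Figure D5:**
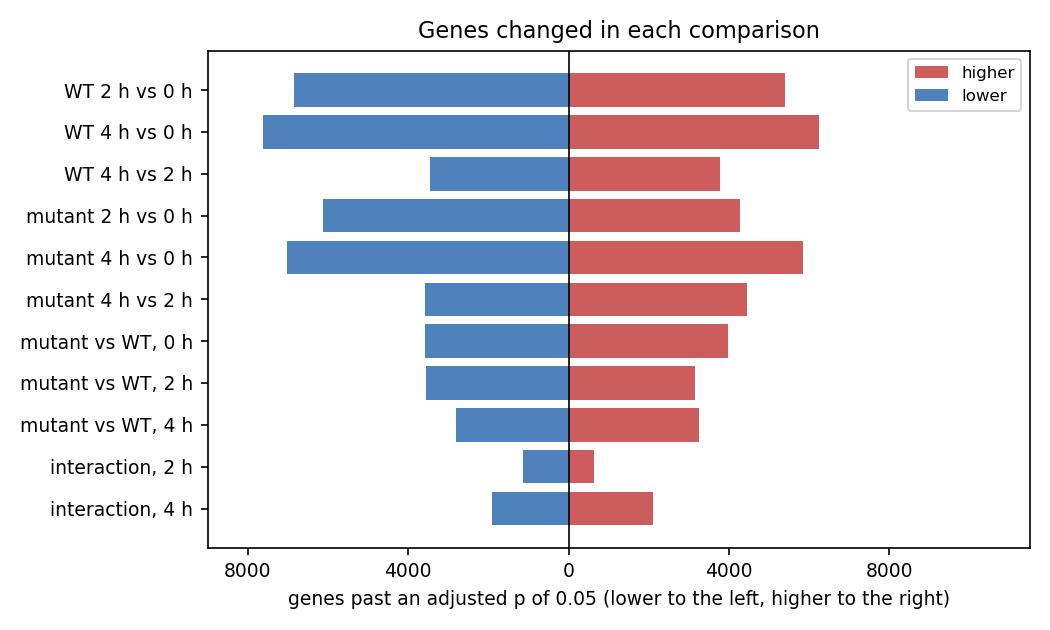
Bars on the horizontal axis show the number of genes higher (right) and lower (left) at an adjusted p under 0.05 in each of the 11 comparisons, the interactions being the differences between responses, of 20372 genes tested. Counts run from 1757 for the difference between responses at 2 h to 13853 for 4 h against 0 h in WT.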

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

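The tests of anther, drying, slide, scan-day and 0 h explanations in this part, and the counts of other splits, were chosen only after the result was seen, while the tests of differences between responses were planned. The results here drew attention because the response to drying differed between the genotypes in a test of that difference, or because a signal appeared in probes that no gene was assigned to.

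A difference here is the mutant response minus the WT response, so its sign does not give the size of a response. At 2 h it was positive for 623 genes and negative for 1134. By list the differences were -1.63 for jasmonate, -1.13 for glucosinolate, -1.36 for ABA receptor, -0.34 for photosynthesis, 0.41 for ABA kinase, 0.39 for senescence and 1.38 for dark and sugar-starvation genes. None of these 7 lists passed with an estimated correlation (adjusted p of 0.471 or more). No cytokinin list passed at 2 h, and of their genes CYP735A1 (-5.80), CYP735A2 (-4.79), IPT3 (-2.67), CKX4 (-3.29) and ARR7 (-1.48) had negative differences and ARR16 (2.47) a positive one. Others with negative differences were CYP82G1 (-5.72), NRT2.6 (-5.11), ARLA1B (-4.81), EXO70H2 (-4.77), the beta-amylase BAM5 (-4.67) and SQP2 (-4.66). LOX2 (-2.24), PAP1 (-2.50), RD20 (-2.31), LTI30 (-2.03) and RD22 (-1.33) rose less in the mutant, and NCED3 (1.87) and NAP (1.55) more. Such differences carry the 0 h difference with the opposite sign, and WT 0 h is alone on slide 1. LOX2, PAP1, RD20 and RD22 stood higher and NCED3 lower in the mutant at 0 h, and NCED3 did not differ past the test at 2 h. Clock genes with a difference were CCA1 (-1.47), LHY (-1.08) and TOC1 (0.63). Other genes with a symbol and positive differences were P1R3 (5.04), OCT1 (5.0), HIPP22 (3.45), GASA3 (3.36), AT14A (3.33), RTFL21 (3.3), PEPC1 (3.22) and ESE1 (3.15). Genes without a symbol reached -7.17 (AT2G44240) and 4.26 (AT1G13670). Of the 16 genes with a symbol and the largest differences, all but AT14A, RTFL21, ARLA1B and BAM5 were below background on at least 1 array of the groups compared, so their fitted values are not exact.

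At 4 h the difference was positive for 2114 genes and negative for 1913. List differences were -1.57 for jasmonate, -1.80 for glucosinolate, -0.77 for ABA receptor, -0.42 for photosynthesis, -0.78 for chlorophyll, -0.52 for ribosomal and 0.63 for ABA kinase genes. With an estimated correlation none of these 7 lists passed (adjusted p of 0.457 or more). Among genes with a symbol, the most negative differences were those of NRT2.6 (-7.86), NRT1.8 (-6.42), ELI3-2 (-6.90), CYP82G1 (-6.63), RLP40 (-5.92), SRO5 (-5.27), ChlAKR (-5.12) and BAM5 (-5.11). The chloroplast heat-shock gene HSP21 (7.09), NUDT24 (7.30), WNK3 (4.89), BGLU28 (4.89), AGP3 (4.83), RL6 (4.66), MYB121 (4.24) and MYB47 (4.21) had the most positive ones. Genes without a symbol reached -6.43 (AT5G43410) and 6.49 (AT1G50930). NCED3 (1.49), CYP707A3 (0.73) and RAB18 (2.33) rose more in the mutant, and HAI1 (-2.77), RD22 (-1.56), RD20 (-2.30), GOLS1 (-2.09), PAP1 (-2.84) and LOX2 (-2.19) less. Of these, NCED3 and RAB18 stood lower and HAI1, RD22, RD20, PAP1 and LOX2 higher in the mutant at 0 h, which these differences carry with the opposite sign. ARR7 (-1.37), CKX4 (-3.41) and IPT3 (-1.59) had negative differences. Clock genes with a difference were CCA1 (-2.04), LHY (-1.93), TOC1 (0.79) and GI (0.73). Of the 16 genes with a symbol and the largest differences, all but MYB47, ELI3-2, ChlAKR and BAM5 were below background on at least 1 array. Outside the genes compared, 1959 of 7128 probes without a locus were well above background on all 18 arrays.

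Anther transcripts such as LAP5 (brightest array 1.52), ACOS5 (0.32) and CYP704B1 (0.18) were high in 5 of the 9 mutant arrays. Not all 10 genes followed this pattern. GRP19 read -7.90 to -6.61 in those arrays, against -5.36 and -4.44 in the other mutant 0 h arrays. QRT3 was raised only in replicate 3 of mutant 0 h (0.49), and A9 also read -2.39 in replicate 3 of mutant 4 h. The genotype alone is argued against by a range of 5.5 within mutant 0 h, against at most 1.03 within a WT group, and the slide or scan day by an excess of at least 5.01 over the mean of the other arrays of the same group on the same slide. Flower bud RNA may be the source: the same arrays stood higher in the floral list by a median of 3.15 in mutant 0 h (9 of 10 genes highest there; floral medians -1.51 against -3.42 and -8.08) and 3.28 in mutant 4 h (8 of 10). WT arrays had floral medians of -4.16 to -2.17 with low anther means (-7.40 to -6.03). Replicate 1 of mutant 2 h had a floral median of -3.44 with a higher anther mean (-3.42). The stage of the buds therefore stays open, as does any effect of the genotype on flowering. The anther list was written after AMS, LAP5 and ACOS5 had been seen, and of its 20 genes 10 could be tested, 3 of them well above background on all 9 WT arrays.

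Jasmonate, glucosinolate and salicylate genes stood higher in the mutant at 0 h, and if its plants were already drying, dehydration genes would have moved by as large a share of their WT 2 h response as jasmonate genes. They moved by 0.132 of it against 0.226, a difference of -0.0946 (95% interval -0.192 to 0.00025), and DREB genes by -0.0277, which is -0.254 from the jasmonate share (95% interval -0.402 to -0.174). These intervals are over genes and hold no spread between arrays or slides, and every share uses the WT 0 h arrays of slide 1 in both of its parts. Within that limit, the DREB share and the lower NCED3 (-1.64) go against drying. RAB18 (-1.58) does so only in replicates 2 and 3 of mutant 0 h, since replicate 1 read 0.91, near the WT arrays (1.03 to 1.23). The PP2C share was 0.153 (95% interval 0.0382 to 0.225), above 0 but below that of the jasmonate genes. The higher RD20 (1.99), RD22 (1.37), HAI1 (2.21), P5CS1 (1.95) and RD29B (1.86) go with drying. With genes below background at their bound the PP2C share was 0.139 (-0.0149 to 0.214), which is -0.0982 from the jasmonate share (-0.259 to -0.00568). The dehydration difference was then -0.13 (-0.224 to -0.0444). Both differences go against drying by this measure. Drying stays open, since no time before 2 h was measured to tell whether the shares of lists start out equal. Slide 1 stays open for jasmonate genes, which lay at -0.61 at 2 h, and for salicylate genes, which stood 0.96 higher at 4 h without it but with 3 of 21 genes past the test and a difference between arrays of 0.88 (95% interval -0.44 to 2.21), and the scan day cannot be told apart from the genotype, since 0 slides or scan days hold both.

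At 4 h the differences between responses were negative for jasmonate and glucosinolate genes. For jasmonate genes, a higher start with an equal end level is argued against as the whole cause, since they lay at -0.61 at 4 h (95% interval over genes -1.02 to -0.31, over arrays -1.06 to -0.26). For glucosinolate genes a higher level at 0 h (1.88) with a similar level at 4 h may account for the difference, since they lay at 0.25 (95% interval over genes -0.10 to 0.40, over arrays -0.50 to 0.68). A direct effect of the disrupted regulators, which was not tested, and the slides stay open for both.

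For comparisons of 3 arrays against 3, 10 splits are too few for a share under 0.05, and in each only 1 split, the real one, called as many genes as it did. Real and highest other counts were 12245 and 0 for WT 2 h against 0 h, 13853 and 0 for WT 4 h against 0 h, and 7220 and 1 for WT 4 h against 2 h. They were 10386 and 51, 12876 and 322, and 8034 and 30 for the same comparisons in the mutant, and 7557 and 1, 6725 and 4, and 6060 and 0 for mutant against WT at 0, 2 and 4 h. For the differences between responses, genotypes were drawn anew among the arrays of each time in 100 splits. At 2 h, 8 splits called as many as the real 1757 genes and the highest other called 4281. At 4 h, 3 splits called as many as the real 4027 and the highest other called 9022. The splits above the real count keep or swap the genotype whole at one time and mix or swap it at the other. They carry the genotype difference itself, a structure of the samples, so these counts decide nothing about chance.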

How the results depend on the processing

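The setting that left out mutant 0 h replicate 3 and mutant 4 h replicate 2 together was chosen after seeing the data, and all other settings were planned. The fall of ARR1, ARR10 and ARR12 kept its direction and stayed past the threshold under every setting in which it was recomputed. Gene counts stayed within 1.5 times those reported in all 11 comparisons with quantile normalization, the array median, normexp, no filter, all-array filter, outlier spots kept, trend and robust, the replicate block and the mean of probes. A minimum of 2-fold gave, for WT 2 h and 4 h against 0 h and 4 h against 2 h, 6088, 7559 and 2259 genes, for the mutant 4674, 6229 and 2452, for mutant against WT at 0, 2 and 4 h 2809, 2269 and 2049, and for the differences between responses 1010 and 1813. A threshold of 0.01 gave 4342 for WT 4 h against 2 h, 4895 for the mutant, 4580, 3390 and 3187 for mutant against WT, and 504 and 1673 for the differences. Both lower counts by construction. Slide as a fixed block gave 2110 (63.3% higher, against 52.3%) for WT 4 h against 2 h, 7268 for mutant 4 h against 0 h and 4082 for 4 h against 2 h. Within one slide limma called 0 (4927 at an unadjusted p under 0.05), 966 for mutant 2 h against 0 h, and 0 (4309), with fewer arrays. There, a lone array is assumed to vary like the others. Slide as a random block (correlation -0.234) gave 10931 and 9501 for mutant against WT at 2 and 4 h, and 3682 and 8199 for the differences. A negative correlation makes the mean of a slide count as more precise, and genotypes differ only between slides. These higher counts therefore add no support to the differences. Array weights gave 13035 for mutant against WT at 0 h, and 4243 and 8472 for the differences. Only the groups compared gave 2965 for mutant 4 h against 2 h, 2432 for mutant against WT at 2 h and 1072 for the difference at 2 h. The authors' table gave 2962 and 2477 for mutant against WT at 2 and 4 h, and TOC1 at 2 h changed sign to 0.058, as that table's genotypes have different baselines by construction. For the other settings the cause was not tested. Lists past camera with an estimated correlation were 0 in each of the 6 time comparisons, 2 (the cytokinin lists) in each of the 3 against WT and 0 in both differences. No filter gave 16 lists for mutant against WT at 0 h, quantile normalization 4 for the difference at 2 h, and for that at 4 h the all-array filter gave 11 and weights 12. Of 121 single list calls, 0 reversed, and between 0 (outlier spots kept, trend and robust) and 13 (array weights) were lost, apart from 115 with an estimated correlation. Overlaps moved as follows: 2-fold gave 3728 genes shared by the genotypes at 2 h and 4835 at 4 h. Genes shared by the 0 h difference and the WT response were 1467 at 2 h and 1577 at 4 h with 2-fold, 2538 and 2621 at 0.01, 7370 and 7918 with weights, and 6664 at 2 h with the random slide block. Leaving out each array kept 194 of 198 gene counts within 1.5 times. The difference at 2 h ranged from 965 to 1974 genes, with 965, 977 and 1043 without WT 0 h replicates 1, 2 and 3 and 1135 without mutant 0 h replicate 2, and from 4 (without WT 2 h replicate 3) to 10 lists. Replicate numbers showed no pairing over all groups: 12 of 45 same-number pairs had r over 0.1, and the median r was 0.002. Single pairs ranged from -0.55 (mutant 0 h and 4 h, replicate 2) to 0.462 (mutant 0 h and 2 h, replicate 3), and pairing within part of the groups was not tested. Without the anther arrays of mutant 0 h and 4 h, 7794 and 6500 genes differed from WT at 0 and 4 h, and 8 of 75 list calls were lost. Scalings moved the median of all genes by over 0.1: the array median by 0.126, 0.121 and 0.19 (WT 4 h, mutant 2 h and 4 h against 0 h), normexp by 0.111 and 0.104 (WT 2 h and 4 h), and no filter by 0.233, 0.186 and -0.103 (WT 2 h, 4 h, and 4 h against 2 h). The share of higher calls moved from 45.4% to 56.6% for mutant 4 h against 0 h and from 52.7% to 42.6% for mutant against WT at 0 h with the array median, from 47.0% to 36.2% with normexp and 36.4% without filter at 2 h, and from 35.5% to 48.0% with quantile normalization and 46.4% with the array median for the difference at 2 h. Dim genes limit precision: between 67.2% and 73.1% of spots per array were well above background.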

Other observations

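No further test was chosen for this part. No cytokinin list passed in drying WT leaves, but single genes changed. After 2 h the cytokinin oxidase CKX4 rose by 3.73 and the type-A regulators ARR9 and ARR5 fell by 1.56 and 1.37 ± 0.203, while ARR7 rose by 0.77. After 4 h the receptor AHK4 stood 1.82 higher and AHK2 fell by 2.21. In the mutant at 2 h, ARR9 and ARR5 fell by 1.60 and 1.65 and IPT3 by 2.23.

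No clock, auxin, sugar-starvation or cell-wall list passed in WT at 2 or 4 h against 0 h, but single genes changed there too. After 2 h PRR9 rose by 2.76 and CCA1 by 2.05, and CHE fell by 3.03. The auxin-response repressor IAA4 fell by 3.12, and the sugar-starvation genes DIN10 and DIN4 fell by 2.62 and 1.83. After 4 h IAA29 fell by 5.45 and EXPA11 by 5.32, while EXPA10, of the same expansin family, rose by 6.07. In the mutant at 4 h LHY fell by 1.92.

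Of the 7128 probes without a locus, 2934 could be tested, and 1582 and 1487 of them changed at 2 h in WT and at 4 h in the mutant. Replicate arrays of WT 0 h had a median SD of 0.0855 per gene, against 0.192 in WT 2 h, 0.132 in WT 4 h, 0.212 in mutant 0 h, 0.236 in mutant 2 h and 0.23 in mutant 4 h. Replicate 2 of mutant 0 h had the lowest floral median of its group, at -8.08, beside -3.42 and -1.51.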
